A study of Homo sapiens with 4 samples.

How the data were processed

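RNA was measured by paired-end sequencing in 4 libraries, 1 for each of the cell lines SU-DHL-1 and Karpas-299 with DMSO or crizotinib. Per the labels' protocols, RNA was isolated on columns, first-strand cDNA was tailed with poly(A) by terminal transferase and amplified by PCR, and the sheared cDNA was amplified again before sequencing on an Illumina HiSeq instrument. No strand-marking step and no molecular identifiers are described there. The dose and duration of crizotinib, the aligner and the treatment of PCR duplicates are not given in the sources used here.

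The deposited files hold raw counts of fragments per gene, which the authors made with featureCounts from Subread 1.5.0, per the file headers. Per the file headers, read pairs were counted as fragments, a fragment was counted for every gene it overlapped, no strand option was set, and the annotation was an Ensembl gene set of GRCh37. Overlapping genes can therefore share fragments, and a gene cannot be separated from an antisense partner. The labels' list of builds names GRCh37 and hg19. Each file holds 62069 genes, with Ensembl identifiers and GRCh37 coordinates but no symbols. Symbols were taken by identifier from a table of gene names, which matched 39289 identifiers, and gene types from the GENCODE annotation of a later build, used for names and types only. Of the genes, 29561 had no count in any library. Library totals ranged from 34916467 to 43452285 counts.

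Groups were taken from the labels. The 2 lines were the only replicates of a treatment, and nothing in the labels describes separate cultures of one line. The only spread available for p-values is therefore that between the lines in their response. For each gene it is pooled with a trend over all genes, which weighs more than the gene's own spread. Genes with 0 counts in both libraries of a line add no spread of their own. The replicate numbers pair the libraries because libraries with the same number come from the same cell line, so the line entered the main model as a block. The model had the terms line and treatment and 1 residual degree of freedom. It was fitted with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest with default options) on TMM-scaled counts of the 18572 genes that passed filterByExpr for the treatment groups, which uses a minimum count of 10. The common dispersion was 0.0473 and the median prior degrees of freedom 4.07. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. The same fit gave the difference between the lines.

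Within a line, the log2 ratio of crizotinib to DMSO was taken from TMM-scaled CPM with a prior count of 2, with a 95% interval for counting error from the exact binomial. A gene with 0 counts in a library was set against 3 counts for a lower bound on its fold change. XIST and genes on chromosome Y were left out of the tables.

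The 27 gene lists, the rule for named genes, the tests and all alternatives but 1 were fixed before the data were examined. The lists cover STAT3 and JAK-STAT targets, ALK-positive lymphoma signature genes, cytokine receptors, MAPK output, AP-1, E2F and replication, mitosis, MYC and ribosome biogenesis, glycolysis and hypoxia, cholesterol synthesis, amino acid response, interferon response, T cell identity, cytotoxic granules, apoptosis regulators, p53 targets, quiescence, NF-kappaB, antigen presentation, and matrix genes. Further lists hold markers of B, myeloid, epithelial, fibroblast and endothelial, and erythroid cells, mitochondrially encoded genes, and immediate early and heat shock genes. UHRF1, ACACA, CCL3, CCL4 and CCL5 had no match by symbol in the files, GARS is an older symbol of more than 1 gene, and these were left out. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. With 1 residual degree of freedom the estimated correlation is itself poorly determined, and that test has almost no power. Camera at an estimated correlation called 0 lists in either comparison (smallest adjusted p = 0.634 and 0.879), so its outcome decides nothing for or against a list. For each line, a list's median was also placed among 10000 random lists of the same size matched on mean expression.

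The rule for named genes took ALK, NPM1, STAT3, OSMR, IL31RA and IL6ST, then up to 12 called genes per direction with the same direction in both lines, a log2 ratio of at least 0.58 in size in each and a mean of at least 5 CPM, filled up to 5 by the smallest p. It added up to 4 members of each list with the smallest p, the 5 largest ratios per direction within each line among genes with at least 100 counts, 10 genes per direction and 3 members per list for the lines, and the 4 genes with the most opposed ratios. Some were left out of the text for length. The called genes without a symbol, and the immunoglobulin genes other than IGHM and IGHA1, CD79A, MS4A1, JCHAIN, VPREB1, LINC00520, KTN1-AS1 and PELI2 in the closing section fall outside this rule and were chosen after values were seen.

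The scripts were tested on simulated data with the real means and library sizes. Counts were drawn per gene at the trended dispersion, with no further spread of a gene or of its response between the lines. The shares called may therefore exceed those in the real data, where CAV1, at 5.98-fold, was not called (adjusted p = 0.0803, edgeR). For crizotinib against DMSO over 18572 simulated genes, 13 of 50 genes changed 2-fold, 46 of 50 changed 4-fold and 48 of 50 changed 8-fold were called, and 8 of 18122 unchanged genes were called. For the lines, the same fit called 11 of 50, 45 of 50 and 47 of 50. Camera called 10 of 10 simulated lists of 25 genes shifted by 0.6 on the log2 scale and 0 of 10 unshifted lists. The simulated genes were independent of each other, so this does not show how often camera calls lists whose genes vary together.

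The alternatives tried were RLE size factors, library totals alone, no low-count filter, at least 1 CPM in all 4 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), 2 other options of the quasi-likelihood fit, leaving the block out, leaving out each library or line, prior counts of 0.5 and 5, and other thresholds. Tables were joined with Python 3.11.15 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9.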

Results

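Gene-level RNA-seq counts were available for 4 libraries from 2 established human cell lines, SU-DHL-1 and Karpas-299. Both lines were derived from anaplastic large-cell lymphoma, a T-cell lymphoma, and carry a fusion of NPM1 to the receptor tyrosine kinase gene ALK. Each line was treated with crizotinib, an inhibitor of the ALK, MET and ROS1 kinases, or with its solvent DMSO, and the study asked how ALK activity shapes the transcriptome of these cells. Each line and treatment had 1 library, so the groups held 2 libraries each and the 2 lines served as the replicates. The libraries held 37621278 (SU-DHL-1, DMSO), 34916467 (SU-DHL-1, crizotinib), 37052507 (Karpas-299, DMSO) and 43452285 fragment counts (Karpas-299, crizotinib). At these depths a count of 0 allowed a level of up to 0.0662 to 0.0843 CPM (counts scaled to the library size), the value of 3 counts. Intervals and floors cover counting error only, since the libraries were amplified by PCR and carry no molecular identifiers. Ratios within a line rest on 1 library against 1 and have no replicate check.

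The first comparison asked which genes responded to crizotinib in both lines. Expression of 7 genes fell with crizotinib, each with lower values in both SU-DHL-1 and Karpas-299. TMEM260 (ENSG00000070269, chromosome 14, 56955072 to 57117324 on GRCh37, plus strand), which encodes a protein O-mannosyltransferase, fell 10.6-fold (log2 −3.41 ± 0.18 SE, n = 2 libraries per group). IL6R, the ligand-binding chain of the interleukin-6 receptor (ENSG00000160712, chromosome 1, 154377669 to 154441926), fell 6.75-fold (log2 −2.75 ± 0.17). EPAS1, the hypoxia-inducible transcription factor HIF-2alpha (ENSG00000116016, chromosome 2, 46520806 to 46613836), fell 5.99-fold (log2 −2.58 ± 0.16). RGS16, an inhibitor of G-protein signalling (ENSG00000143333, chromosome 1, 182567758 to 182573543), fell 13-fold (log2 −3.70 ± 0.23).

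These 4 genes and 3 genes without a symbol at the TMEM260 locus had an adjusted p = 0.0440 (edgeR quasi-likelihood test with the cell line as a block, Benjamini-Hochberg over 18572 genes). TMEM260 went from 569 to 59.4 CPM in SU-DHL-1 and from 412 to 35.2 CPM in Karpas-299. IL6R went from 470 to 65.0 CPM and from 69.2 to 11 CPM, and EPAS1 from 828 to 143 CPM and from 98.1 to 15.8 CPM. RGS16 went from 355 to 24.7 CPM in SU-DHL-1, but its Karpas-299 value rests on 61 and 8 counts. The 3 genes without a symbol were ENSG00000258803 (56981049 to 57018027, a lincRNA gene), ENSG00000258428 (57099962 to 57115376) and ENSG00000259133 (57115683 to 57197253), the last 2 annotated as antisense to TMEM260. The antisense genes share 99 and 164 exonic bases with TMEM260, and the counting used no strand, so their fragments cannot be told apart from those of TMEM260. No gene was called higher by edgeR. At an unadjusted p under 0.05 there were 3662 genes (1838 higher and 1824 lower), where 929 in both directions together were expected by chance. limma-voom also called 0 genes higher, whereas DESeq2 called 260 higher and 687 lower.

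The calls lay near the threshold: 0 genes passed with RLE size factors, with library totals as the only scaling, with a filter of 1 CPM in all 4 libraries, with edgeR's newer quasi-likelihood method or without the cell line as a block. All 7 remained among 867 genes (311 higher, 556 lower) called without a low-count filter and among the 947 that DESeq2 called.

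The genes closest to the threshold in the other direction were IRAG2, CAV1 and SERTAD2. IRAG2 had a log2 fold change of 3.30 ± 0.24 (adjusted p = 0.0732, edgeR), CAV1, the main protein of caveolae, 2.58 ± 0.21 (adjusted p = 0.0803), and SERTAD2, a transcriptional coregulator, 1.83 ± 0.16 (adjusted p = 0.0816). In SU-DHL-1, the IRAG2 value rests on 5 and 66 counts and that of CAV1 on 19 and 107. IGHM followed with an adjusted p = 0.0965, from Karpas-299 alone, since it had 0 counts in both SU-DHL-1 libraries. Its p-value therefore measures no spread of IGHM between the lines. Among genes with higher values in both lines and a mean of at least 5 CPM, the rule for named genes next took TUBB2A at 1.71 ± 0.18 and CSGALNACT1 at 2.18 ± 0.26, the latter on 1 and 3 counts in SU-DHL-1. Among lower values, AQP9, an aquaporin, stood at −2.34 ± 0.17 with an adjusted p = 0.0732. At an adjusted p under 0.1, 4 genes were higher and 37 lower. Some named genes share exons with another counted gene, so part of their counts is uncertain. The partner's counts equalled 80.9% of those of RUBCNL and 11.3% to 22.2% of those of IRAG2, AQP9, IL6ST, IL2RA, GNL3, BLK and CD44.

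**Figure D1:**
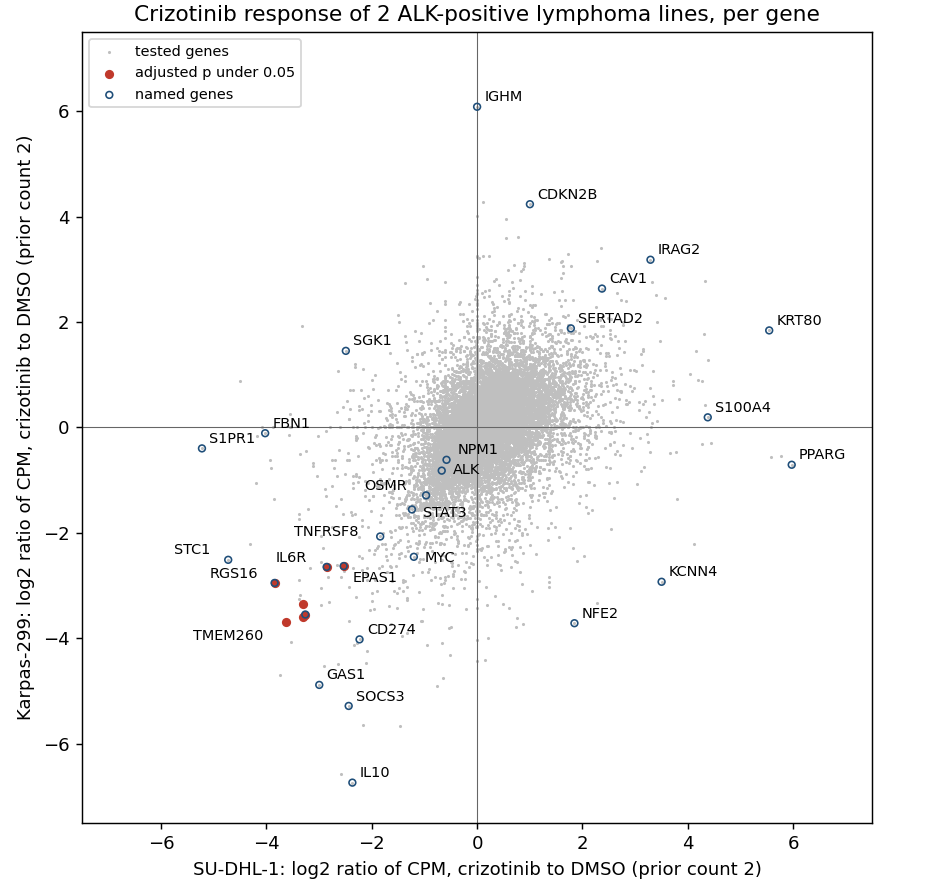
Each point is a gene tested, placed by its log2 ratio of crizotinib to DMSO in SU-DHL-1 (x axis) and Karpas-299 (y axis), with red points for the 7 genes with an adjusted p under 0.05 and blue rings for named genes. TMEM260, IL6R, EPAS1 and RGS16 lie far down in both lines, while KCNN4 and NFE2 lie on opposite sides of 0 and PPARG and IGHM stand apart in 1 line.

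The drug target and the genes of interest to the study had lower values in both crizotinib libraries, but none of them passed the test over all genes. ALK was at 568 CPM with DMSO and 357 CPM with crizotinib in SU-DHL-1, and at 255 and 144 CPM in Karpas-299 (log2 −0.75 ± 0.15, adjusted p = 0.134, edgeR). NPM1, the fusion partner and a nucleolar chaperone, had a log2 fold change of −0.60 ± 0.13 (adjusted p = 0.138). The counts are per gene and do not separate the fusion transcript from either gene. STAT3, a transcription factor activated downstream of ALK, stood at −1.40 ± 0.16 (adjusted p = 0.115). OSMR, a subunit shared by the receptors for oncostatin M and interleukin-31, stood at −1.13 ± 0.18 (adjusted p = 0.119), and it shares exons with RICTOR, whose counts equalled 45.2% of its own. IL6ST, the signalling chain gp130, stood at −0.89 ± 0.19 (adjusted p = 0.137). IL31RA, the other subunit of the interleukin-31 receptor, had within-line log2 ratios of −0.73 in SU-DHL-1 and −0.13 in Karpas-299 (adjusted p = 0.394).

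**Figure D2:**
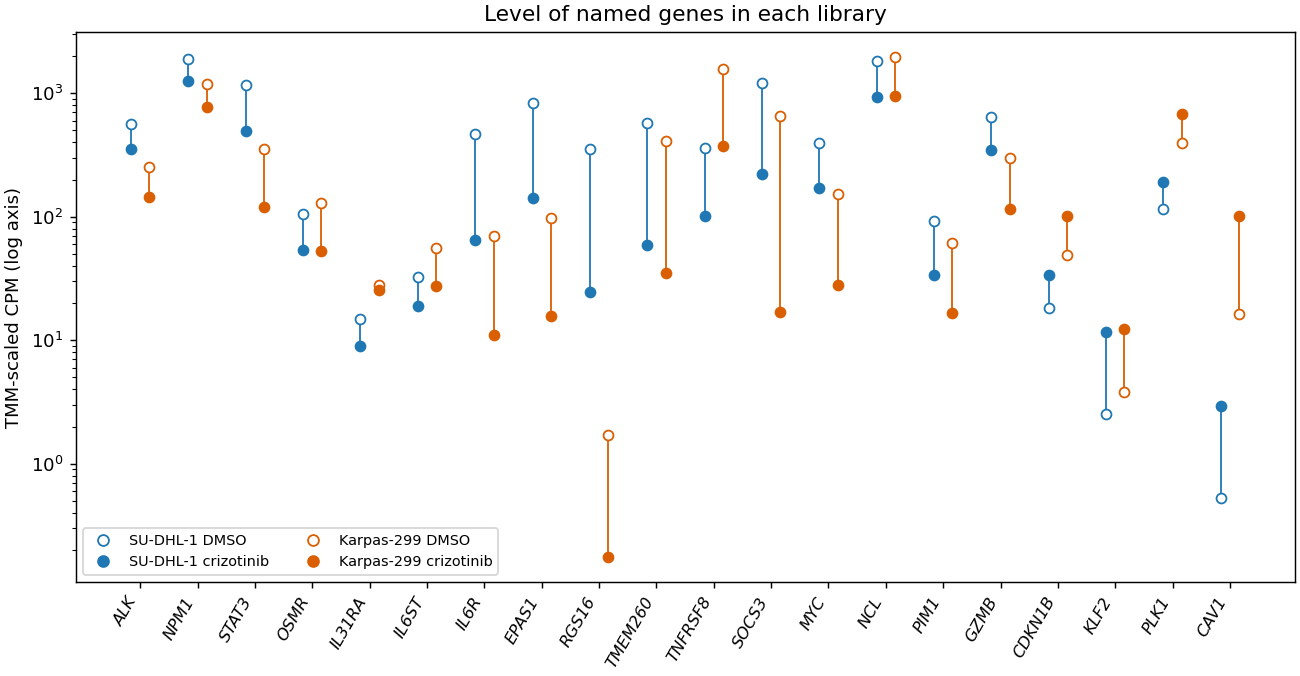
TMM-scaled CPM on a log axis for 20 named genes in the 4 libraries, with open circles for DMSO and filled circles for crizotinib, blue for SU-DHL-1 and orange for Karpas-299, and a line joining the 2 libraries of a line. In Karpas-299, IL31RA stood at 28.0 and 25.6 CPM with DMSO and crizotinib, and SOCS3 at 660 and 16.9 CPM.

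STAT3 and JAK-STAT target genes fell as a list, with a median log2 fold change of −1.41 over 28 genes (camera with a preset correlation of 0.01, adjusted p = 9.35e-20). With an estimated correlation the list did not pass (adjusted p = 0.634). Here and below, that test decides nothing, since 1 residual degree of freedom leaves it almost no power. The list did not pass fry either (adjusted p = 0.399). Camera at the preset correlation takes the genes of a list as almost independent, so genes that vary together can make its p-values too small. This list call and those below rest on that assumption. Of the list's members, 18 were lower and 1 was higher when adjusted over the list alone, and 0 passed over all genes tested. TNFRSF8, which encodes the diagnostic surface antigen CD30, had a log2 fold change of −1.95 ± 0.15, and the kinase gene PIM1 −1.68 ± 0.20. SOCS3, the feedback inhibitor of JAK kinases, went from 1199 to 221 CPM in SU-DHL-1 and from 660 to 16.9 CPM in Karpas-299. The list median was −0.94 in SU-DHL-1 and −1.61 in Karpas-299, at percentile 0 of 10000 random lists matched on expression in each line.

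ALK-positive lymphoma signature genes, taken from general knowledge of the disease, also fell as a list (27 genes, median −1.48, camera adjusted p = 1.25e-15). Their adjusted p = 0.634 with an estimated correlation. Members numbered 17 lower and 1 higher when adjusted over the list alone, and 0 over all genes tested. The list shares TNFRSF8, BCL6, CEBPB, GZMB, IL2RA and CCND3 with the STAT3 list. Other lists overlap too, with TNFRSF8 and IL2RA among the cytokine receptors and MYC on the STAT3, MAPK and MYC lists. The calls of these lists are therefore not independent. IL1RAP, an accessory chain of the interleukin-1 receptor, stood at −2.02 ± 0.21, IL2RA, the interleukin-2 receptor alpha chain CD25, at −2.23 ± 0.28, and the transcriptional repressor BCL6 at −2.56 ± 0.32. Receptors of the interleukin-31 and oncostatin M family and other cytokine receptors fell as a list (25 genes, median −1.13, camera adjusted p = 4.13e-08). The estimated correlation again gave an adjusted p = 0.634. Within that list 16 genes were lower and 6 higher when adjusted over the list alone, so its members went both ways, and 1 of them, IL6R, passed over all genes tested. IFNGR1, a chain of the interferon-gamma receptor, stood at −1.75 ± 0.18.

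MYC and ribosome biogenesis genes showed the smallest camera p of the lists (28 genes, median −1.12, adjusted p = 3.07e-28). The adjusted p of this list was 0.634 with an estimated correlation and 0.367 with fry. All 28 had lower values in both lines, 26 were lower when adjusted over the list alone, and 0 passed over all genes tested. MYC itself stood at −1.83 ± 0.33, with 394 and 171 CPM in SU-DHL-1 and 153 and 27.8 CPM in Karpas-299. The nucleolar genes NOLC1 (−1.52 ± 0.16), GNL3 (−1.23 ± 0.15) and NCL (−1.01 ± 0.13) were among its members. Glycolysis and hypoxia genes fell with a smaller median of −0.36 (28 genes, camera adjusted p = 1.01e-04, and 0.634 as the adjusted p with an estimated correlation). When adjusted over the list alone 4 were lower, and 0 passed over all genes tested. PFKFB3, an activator of glycolysis, stood at −2.13 ± 0.17, the hexokinase gene HK2 at −1.64 ± 0.23 and the lactate dehydrogenase gene LDHA at −0.81 ± 0.14.

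Transcripts downstream of growth-factor signalling fell as lists too. MAPK pathway output genes had a median of −1.11 over 19 genes (camera adjusted p = 9.41e-08) and AP-1 genes −1.08 over 13 genes (camera adjusted p = 4.61e-08). Both had an adjusted p = 0.634 with an estimated correlation. When adjusted over the list alone, 11 MAPK genes were lower and 1 was higher, 8 AP-1 genes were lower, and 0 of either list passed over all genes tested. SPRY4, a feedback inhibitor of the pathway, stood at −1.52 ± 0.25, and EGR1 at −1.51 ± 0.30. BATF, an AP-1 factor of lymphocytes, stood at −1.91 ± 0.23 and FOSL2 at −1.08 ± 0.18. NF-kappaB and inflammatory genes fell with a median of −0.57 over 19 genes (camera adjusted p = 9.81e-05, and 0.634 as the adjusted p with an estimated correlation). Of them 6 were lower when adjusted over the list alone and 0 over all genes tested. Their median was −0.17 in SU-DHL-1 (percentile 4.44 of the random lists) and −0.77 in Karpas-299 (percentile 0). Lower values in both lines were found for 9 of them and higher values in both for 0. BIRC3, an inhibitor of apoptosis, stood at −1.89 ± 0.22 and NFKBIA at −1.18 ± 0.25. Cytotoxic granule genes fell with a median of −0.33 over 13 genes (camera adjusted p = 0.00926, and 0.634 as the adjusted p with an estimated correlation), with 2 lower when adjusted over the list alone and 0 over all genes tested. The granzyme gene GZMB stood at −1.13 ± 0.18. This last call ended with a filter of 1 CPM in all 4 libraries (adjusted p = 0.102) and without the cell line as a block (adjusted p = 0.101).

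The cell-cycle lists went in opposite directions. E2F and DNA replication genes fell by a small amount (33 genes, median −0.38, camera adjusted p = 2.94e-05), with an adjusted p = 0.634 with an estimated correlation. Lower values in both lines were found for 24 of them, 1 was lower when adjusted over the list alone, and 0 passed over all genes tested. CDC25A, a phosphatase that drives entry into S phase, stood at −1.22 ± 0.18 and the replication licensing gene CDC6 at −0.89 ± 0.17. Mitosis genes rose as a list (31 genes, median 0.34, camera adjusted p = 1.04e-04), with an adjusted p = 0.675 with an estimated correlation. Higher values in both lines were found for 25, but 0 passed when adjusted over the list alone or over all genes tested. The mitotic kinase gene PLK1 stood at 0.74 ± 0.15 and the cyclin gene CCNB2 at 0.67 ± 0.18. Quiescence and FOXO target genes rose (22 genes, median 0.64, camera adjusted p = 6.57e-04), with an adjusted p = 0.634 with an estimated correlation. When adjusted over the list alone 7 were higher and 1 lower, and 0 passed over all genes tested. KLF2, a transcription factor of resting T cells, stood at 1.95 ± 0.28, CCNG2 at 1.57 ± 0.30 and CDKN1B, the cyclin-dependent kinase inhibitor p27, at 0.96 ± 0.17, whereas BCL6 stood at −2.56 ± 0.32.

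Mitochondrially encoded genes, fixed as a measure of RNA quality, rose with crizotinib in the same libraries (13 genes, median 0.37, camera adjusted p = 0.0132, and 0.811 as the adjusted p with an estimated correlation). All 13 had higher values in both lines, while 0 passed when adjusted over the list alone or over all genes tested. Their share of counts was 1.24% and 1.62% in SU-DHL-1 and 3.50% and 5.17% in Karpas-299, with DMSO and crizotinib respectively. The call ended without the cell line as a block (adjusted p = 0.112). Across the lists, 13 of the 24 tested passed camera (3 higher, 10 lower) and 0 passed fry. The smallest adjusted p of fry was 0.109, for B cell markers, which did not pass camera. The 13 lists that passed camera had an adjusted p of 0.367 or more with fry. With an estimated correlation 0 passed, in a test with almost no power.

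**Figure D3:**
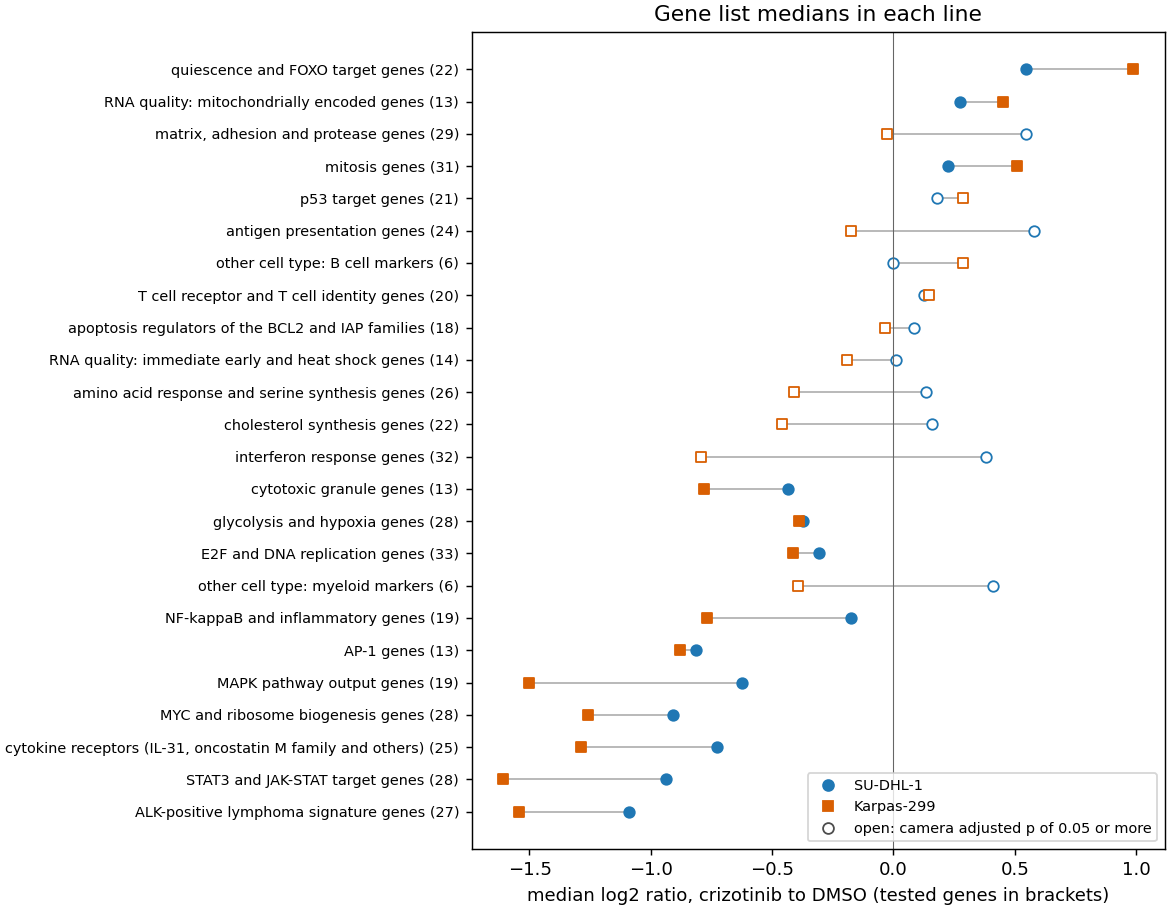
Median log2 ratio of crizotinib to DMSO for each of 24 gene lists, with blue circles for SU-DHL-1 and orange squares for Karpas-299, filled where camera with a preset correlation gave an adjusted p under 0.05. The STAT3 list lies at −0.94 and −1.61, the MYC and ribosome biogenesis list at −0.91 and −1.26, and the mitosis list at 0.23 and 0.51.

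Apoptosis regulators and p53 target genes did not pass as lists. The 18 BCL2 and IAP family genes had a median of 0.05, a mean of −0.04 and a camera test in the lower direction (adjusted p = 0.591), with 2 higher and 2 lower when adjusted over the list alone. BCL2A1, an antiapoptotic BCL2 relative, stood at −2.64 ± 0.21 and the proapoptotic genes BBC3 (PUMA) and PMAIP1 (NOXA) at 1.23 ± 0.24 and 0.81 ± 0.17. The 21 p53 target genes had a median of 0.27 (camera adjusted p = 0.266), with 5 higher and 3 lower when adjusted over the list alone. None of either list passed over all genes tested.

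Within SU-DHL-1, the nuclear receptor gene PPARG and keratin genes were among those with the largest higher values with crizotinib. PPARG had 0 and 117 counts, which puts it at least 38.7-fold higher, and the epithelial keratin gene KRT80 had 181 and 8600 counts (log2 5.54, 95% interval 5.35 to 5.78 from the exact binomial for counting error). S100A4, a calcium-binding protein gene, had a log2 ratio of 4.38. Among the largest lower values were those of S1PR1, the sphingosine-1-phosphate receptor of lymphocyte egress, at −5.22 (interval −5.59 to −4.94), STC1 at −4.72, PTPRB at −4.50 and the fibrillin gene FBN1 at −4.02. S1PR1 and FBN1 had ratios of −0.40 and −0.11 in Karpas-299.

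Within Karpas-299, the largest higher values included those of IGHM, the immunoglobulin mu constant region (18 and 1716 counts, log2 6.09, interval 5.56 to 6.98), RASGRP3 (4.28), the cell-cycle inhibitor gene CDKN2B (4.24) and IGHA1 (4.01). The largest lower values included those of the cytokine gene IL10 (448 and 3 counts, log2 −6.74, interval −9.86 to −6.02), the Toll-like receptor gene TLR10 (−5.66), SOCS3 (−5.28), GAS1 (−4.88) and RUBCNL (−4.75). IL10, SOCS3 and GAS1 had ratios of −2.37, −2.44 and −3.0 in SU-DHL-1. Whether the lines differed in response was not tested, since the model with that term leaves no residual degree of freedom.

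Across genes, the log2 ratios of the lines went together, with Pearson r = 0.418 and Spearman rho = 0.450 over 18572 genes, which are not independent replicates. The ratios share no library. Among 12098 genes with at least 100 counts in both lines, 203 had at least 2-fold lower values in both lines, against 21.7 from independent lists, and 130 had at least 2-fold higher values in both, against 20.1. Ratios of at least 2-fold in opposite directions were found for 22 genes, against 49.8 from independent lists.

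The second comparison took the difference between the lines, with treatment as the block. The lines differed widely: 4185 genes were higher in SU-DHL-1 and 4023 higher in Karpas-299 among 18572 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). These made up 44.2% of the genes tested, the share to set beside the counts of list members below. Antigen presentation genes were higher in Karpas-299, where 21 of 24 passed and 1 passed in the other direction (22 of 24 either way over all genes tested, 23 when adjusted over the list alone). HLA-DRB1, a class II gene, had 1722 and 1560 CPM in Karpas-299 and 1.14 and 3.03 CPM in SU-DHL-1, and the class I gene HLA-B was 9.53-fold higher (log2 −3.25 ± 0.14 for SU-DHL-1 against Karpas-299, adjusted p = 3.36e-04, edgeR). HLA genes have near-identical copies, so their counts are uncertain. The list passed camera (adjusted p = 4.06e-14, and 0.879 as the adjusted p with an estimated correlation) but not fry (adjusted p = 0.2085). Of the 24 lists tested between the lines, 9 passed camera and 0 passed fry. The smallest adjusted p of fry was 0.151, for T cell identity genes.

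T cell receptor and T cell identity genes were higher in Karpas-299 in 11 cases and lower in 5 of 20 (camera adjusted p = 0.00188, and 0.879 as the adjusted p with an estimated correlation), with the same counts when adjusted over the list alone. CD4 stood at 498 and 563 CPM in Karpas-299 and at 0.111 and 0.275 CPM in SU-DHL-1. CD247, the zeta chain of the T cell receptor complex, had 0 counts in both SU-DHL-1 libraries and was at least 578-fold higher in Karpas-299. The transcription factor gene LEF1 went the other way, with 178 and 26.3 CPM in SU-DHL-1 and 1 count in Karpas-299. ITGA4, the integrin alpha-4 chain, was at 891 and 1980 CPM in Karpas-299 against 0.417 and 0.633 CPM in SU-DHL-1, and the hyaluronan receptor gene CD44 at 0.141 and 0.110 CPM against 341 and 197 CPM. IL22 was expressed at 512 and 121 CPM in Karpas-299 and at 0.139 and 0.0826 CPM in SU-DHL-1. STAT3 was 3.68-fold higher in SU-DHL-1 (log2 1.88 ± 0.16, adjusted p = 0.00141) and TNFRSF8 3.98-fold higher in Karpas-299 (log2 −1.99 ± 0.15, adjusted p = 0.00109).

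Amino acid response and serine synthesis genes were higher in SU-DHL-1 in 13 of 26 cases and lower in 4 (15 and 4 when adjusted over the list alone). PHGDH, the first enzyme of serine synthesis, was at 71.3 and 109 CPM in SU-DHL-1 and 0.0281 and 0.0221 CPM in Karpas-299, and PSAT1, a later enzyme, at 73.1 and 73.8 CPM against 0.0281 and 0.110 CPM. MYC and ribosome biogenesis genes were higher in SU-DHL-1 in 11 of 28 cases and lower in 0 (10 and 0 when adjusted over the list alone), among them FBL, a nucleolar methyltransferase, by 4.85-fold. The share of this list called was below the 44.2% of all genes tested. The p53 target genes were higher there in 10 of 21 cases and lower in 2 (10 and 3 when adjusted over the list alone), with CDKN1A, the inhibitor p21, 11.8-fold higher. NF-kappaB and inflammatory genes were higher in Karpas-299 in 10 of 19 cases and lower in 2 (12 and 3 when adjusted over the list alone), although CD40 stood at 13.3 and 14 CPM in SU-DHL-1 against 0.0281 and 0.0221 CPM. These lists passed camera with adjusted p = 0.0437, 0.0437, 0.0436 and 0.0475, and with an estimated correlation each had an adjusted p = 0.879. Mitochondrially encoded genes were higher in Karpas-299 in 13 of 13 cases, over all genes tested and adjusted over the list alone (camera adjusted p = 7.96e-05, and 0.879 as the adjusted p with an estimated correlation).

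Markers of other cell types differed between the lines as well. Among 6 B cell markers tested, 3 were higher in Karpas-299 and 2 in SU-DHL-1 (the same when adjusted over the list alone), and the list passed camera (adjusted p = 0.00540, and 0.879 as the adjusted p with an estimated correlation). PAX5, the B cell commitment factor, was at 91.2 and 38.1 CPM in Karpas-299 and at 0.0555 and 0.0551 CPM in SU-DHL-1, and BLK, a B cell kinase, at 38.5 and 134 CPM against 0.0278 and 0.0826 CPM. Among 6 myeloid markers, 3 were higher in SU-DHL-1 and 1 in Karpas-299, likewise over the list alone (camera adjusted p = 0.0437, and 0.879 as the adjusted p with an estimated correlation), led by the matrix proteoglycan gene VCAN at 212 and 38.9 CPM against 0.113 and 0.0662 CPM. The number of genes differing between the lines was 5363 in a fit with no treatment term, and 2555 to 4069 when 1 library was left out of that fit. It was 4402 with a filter of 1 CPM in all 4 libraries, which removes genes silent in 1 line. With that filter the camera calls ended for T cell identity (adjusted p = 0.475), amino acid response (0.270) and NF-kappaB genes (0.0553, and 0.0546 with RLE size factors), and without any low-count filter the call ended for myeloid markers (0.0972). Each line had 1 library per treatment, so the only spread available is that of the response to treatment between the lines. With 1 residual against a median of 4.07 prior degrees of freedom, these p-values rest mostly on the trend over all genes. For genes with 0 counts in both libraries of a line, such as CD247, they measure no such spread of the gene itself.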

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

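No test was chosen for these results, which are differences between the lines given as values. Each gene or list had crizotinib to DMSO ratios of opposite sign in SU-DHL-1 and Karpas-299, with 1 library per line and treatment, and no difference between the lines was tested. Genes near 0 or lists with members going both ways can meet this rule by small margins.

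PPARG, the nuclear receptor gene, differed by 6.68 (log2, SU-DHL-1 minus Karpas-299, from 5.97 and −0.71). Its SU-DHL-1 ratio rests on 0 and 117 counts and is set by the prior count, so the size of its difference is uncertain. KCNN4, a calcium-activated potassium channel gene on the MAPK output list, differed by 6.43 (3.50 and −2.93), with 17.5 and 199 CPM in SU-DHL-1 and 27.7 and 3.60 CPM in Karpas-299. NFE2, a transcription factor gene of blood cells, differed by 5.56 (1.85 and −3.71), and STAT4, which transmits interleukin-12 signals, by 4.44 (1.90 and −2.54), sharing exons with an antisense gene whose counts equalled 18.6% of its own. SGK1, a kinase gene induced by glucocorticoids, differed in the other direction, by −3.94 (−2.49 and 1.45). CSF1R, the receptor of a macrophage growth factor, differed by 3.10 (0.67 and −2.43), and the mucin gene MUC1 by 2.30 (0.65 and −1.65). MUC1 shares exons with KRTCAP2, whose counts equalled 177% of its own, so its ratios are uncertain.

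Among the lists, interferon response genes had the largest difference of medians (1.18, from 0.38 in SU-DHL-1 and −0.79 in Karpas-299). Myeloid markers differed by 0.80 (0.41 and −0.39), antigen presentation genes by 0.75 (0.58 and −0.17), cholesterol synthesis genes by 0.62 (0.16 and −0.46), matrix, adhesion and protease genes by 0.57 (0.55 and −0.03) and amino acid response genes by 0.54 (0.14 and −0.41). B cell markers differed by −0.29 (−0.0032 and 0.29), immediate early and heat shock genes by 0.20 (0.0093 and −0.19) and apoptosis regulators by 0.118 (0.08 and −0.03). None of these lists passed camera for crizotinib against DMSO.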

How the results depend on the processing

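The count of loci with shared exons taken once was chosen after the result was seen. The other alternatives were planned.

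The number of genes called for crizotinib against DMSO (7) depended most on the processing. It was 0 with RLE size factors, 0 with library totals alone, 0 with a filter of 1 CPM in all 4 libraries, where 6 of the 7 genes were tested, and 0 with the newer quasi-likelihood method. The smallest adjusted p in these fits was 0.107, 0.0525, 0.141 and 0.0823, against 0.0440. It was 867 without a low-count filter and 947 with DESeq2, which gave no adjusted p for 6121 genes, and both included the 7. It was 41 at an adjusted p under 0.1 and 3662 at an unadjusted p under 0.05. It stayed 7 with limma-voom, with robust estimation and without mitochondrial and the 10 most abundant genes, and was 5 with loci of shared exons counted once. It was also 7 at a 2-fold minimum, which could remove none of them, since the smallest change among the 7 was 5.99-fold (EPAS1). Other thresholds give other counts by construction, and for the other alternatives the cause was not tested.

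The lines pair the libraries. Without the cell line as a block, 0 genes were called (277 at an unadjusted p under 0.05, edgeR) and 11 lists passed instead of 13, the cytotoxic and mitochondrial lists being lost. The log2 fold change of PPARG turned there (−0.57), as did the directions of the tests of antigen presentation genes (median −0.147) and B cell markers (median 0.113), none of which passed in either fit. The block changed no other list call for crizotinib. With each library left out in turn the fit had no block either and called 0 to 0 genes, which says nothing on stability, since it called 0 with all 4 libraries.

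The number of genes differing between the lines (8208) was 4402 with the 1 CPM filter, which tests fewer genes, 5363 without the treatment term, and 2555 (without Karpas-299 crizotinib) to 4069 (without Karpas-299 DMSO) with a library left out of that fit, where the lone library of a line is assumed to vary like the other line. It ranged over 6510 to 8974 with the other scalings, no filter and the other tools or options. List tests between the lines gave 4 calls with the 1 CPM filter instead of 9, 3 calls having been lost and the B cell and myeloid lists being too short to test there. The direction of the list test turned for B cell markers with library totals (median 0.258), for apoptosis regulators with the 1 CPM filter (0.159), for the STAT3 list between the lines without a filter (0.345) and for cytotoxic genes between the lines with the 1 CPM filter (0.527), where no adjusted p passed. The cause was not tested. For crizotinib, matrix genes passed without a filter (adjusted p = 0.0491) and with the 1 CPM filter (0.0300), and interferon (0.0293) and immediate early and heat shock genes (0.0228) passed without a filter. Between the lines, cytokine receptor (0.0366), interferon (0.0365), apoptosis (0.0294) and quiescence lists (0.0472) passed without a filter. Library totals alone moved the median of all genes by 0.120 on the log2 scale for crizotinib.

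The correlation of the lines' ratios (0.418) was 0.380 with a prior count of 0.5, 0.430 with 5, 0.506 with the 1 CPM filter and 0.508 over genes with at least 100 counts in every library. Over named genes and settings for crizotinib, 1199 values kept their side of the threshold, 152 passed only under the alternative, 19 passed only in the chosen fit and 28 untested values moved. For low genes such as RGS16 in Karpas-299, depth limits the ratio.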

Other observations

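The tests of shared fragments at the TMEM260 locus and of B or plasma cells were chosen only after the result was seen. Lists that did not pass camera for crizotinib against DMSO still held genes with large values, none of which passed over all genes tested. Interferon response genes (32 tested, median −0.20, camera adjusted p = 0.245, 1 lower when adjusted over the list alone) held MX1, an antiviral GTPase gene, which went from 132 to 12.2 CPM in Karpas-299 and had 4 and 1 counts in SU-DHL-1, and which shares exons with a gene whose counts equalled 13.8% of its own. Antigen presentation genes (24, median 0.23, adjusted p = 0.482, 1 higher and 1 lower adjusted over the list alone) held CD274, the checkpoint ligand PD-L1, which went from 189 to 40.3 CPM in SU-DHL-1 and from 72.8 to 4.43 CPM in Karpas-299 (log2 −3.11 ± 0.47, adjusted p = 0.119, edgeR). T cell identity genes (20, adjusted p = 0.836, 1 higher and 2 lower adjusted over the list alone) had a median of 0.06, a mean of −0.09 and a test in the lower direction, and held CD5, an inhibitory coreceptor, at −1.43 ± 0.17. Matrix, adhesion and protease genes (29, median 0.35, adjusted p = 0.0630, 9 higher and 4 lower adjusted over the list alone) held ITGA4 at 0.99 ± 0.20 and EMP1 at 0.83 ± 0.17.

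Amino acid response and serine synthesis genes (26 tested, median −0.08, adjusted p = 0.202, 1 higher and 5 lower adjusted over the list alone) held the leucine transporter gene SLC7A5 at −1.90 ± 0.29 and the neutral amino acid transporter gene SLC1A4 at 1.32 ± 0.18. Cholesterol synthesis genes (22, median −0.14, adjusted p = 0.427, 0 adjusted over the list alone) held INSIG1, a regulator of sterol sensing, at 0.81 ± 0.15 and the enzyme gene IDI1 at −0.65 ± 0.19, which shares exons with IDI2-AS1 (14.2% of its counts). Immediate early and heat shock genes (14, median −0.02, adjusted p = 0.0755, 4 lower adjusted over the list alone) held FOS at −2.49 ± 0.32. B cell markers (6, median 0.14, adjusted p = 0.987, 1 higher and 2 lower adjusted over the list alone) held BLK, which went from 38.5 to 134 CPM in Karpas-299. Myeloid markers (6, median −0.52, adjusted p = 0.266, 1 lower adjusted over the list alone) held VCAN, which went from 212 to 38.9 CPM in SU-DHL-1. Of the lists too short to test, 4 epithelial markers had a median of −0.04, 2 fibroblast and endothelial markers 1.38 (1 higher adjusted over the list alone) and 2 erythroid markers 0.14. Between the lines, the STAT3 list had a median of 0.38 and a mean of −0.35, and the cholesterol list a median of −0.63 and a mean of 0.34, neither passing.

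Of the 7 genes that fell with crizotinib, 4 lay at the TMEM260 locus. A drop of the whole region is argued against by the 9 neighbours within 1 Mb. Their median log2 ratios were −0.154 in SU-DHL-1 and 0.151 in Karpas-299, or −0.09 and 0.21 over the 8 that were not called. However, LINC00520 stood at −2.39 and KTN1-AS1 at −1.05 in Karpas-299. PELI2 went opposite ways, at −1.10 in SU-DHL-1 and 1.64 in Karpas-299. The ratio of an antisense gene's counts to those of TMEM260 varied by at most 1.20 times over the 4 libraries, and both antisense genes share exonic bases with it, so their counts may be fragments of TMEM260 counted again. For the lincRNA gene the ratio varied by 2.04 times and no exonic base is shared, but a fragment with 1 read in each gene would be counted for both, and whether its counts come from TMEM260 stays open. A response of the locus to crizotinib remains open as well and was not tested apart from these.

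The immunoglobulin heavy chain genes IGHM (0.506 and 37.9 CPM with DMSO and crizotinib) and IGHA1 (0.956 and 16.1 CPM) were higher in the Karpas-299 crizotinib library than in the other libraries, while IGHA2 had 124 counts there, IGHE 18, IGHD 5, IGHG2 5, IGHG4 2, and IGHG1 and IGHG3 0. As far as IGKC, CD79A, MS4A1 and JCHAIN go, mature B or plasma cells are argued against by their sum, 0.949 CPM or 2.51% of the IGHM level. Within that sum, IGKC rose from 1 to 36 counts with crizotinib. Of the B cell markers outside it, BLK (38.5 to 134 CPM) and EBF1 (10.9 to 15.8 CPM) rose in Karpas-299 and PAX5 (91.2 to 38.1 CPM) fell. IGLL1, a surrogate light chain gene of B cell precursors that is not in that sum, went from 0.0281 to 5.14 CPM (1 and 233 counts), while its partner VPREB1 had 0 counts, and RNA of such precursors was not tested and stays open. No counted gene shares exons with IGHM. Some other immunoglobulin constant genes, such as IGHA1 and IGHA2, have near-identical copies, so the counts of those are uncertain. A response of Karpas-299 to crizotinib may underlie the higher values, a hypothesis that rests on 1 library.

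The ratios of the lines went together across genes (r = 0.418). A trend with gene length or abundance common to the crizotinib libraries is argued against as the whole cause, since r was 0.398 after loess trends on both were removed. A response to crizotinib common to both lines may be the source, and a difference in handling between DMSO and crizotinib cultures stays open, since no label describes it.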
